A study of Homo sapiens with 5 samples.

How the data were processed

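DNase-seq peak lists of 5 human cell lines were used, with 3 Hodgkin lines (L1236, L428 and L591) and 2 non-Hodgkin lines (Reh and Namalwa), grouped by the lymphoma type in the labels. All had been used at passage 7. Nuclei were digested with DNase I at 6 U/ml (L1236, L428, Reh) or 12 U/ml (L591, Namalwa), per the labels. The labels state that digestion was tuned for each line to a comparable extent. A growth note in the labels spells 1 Hodgkin line differently from its title, and the title was followed.

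Reads were mapped with Bowtie 1.00 to hg18, per the submitters' processing notes. Reads were elongated to 146 bp and placed in 10 bp bins, per the columns of the files. The peak caller, its threshold and the read depth are not given in the sources used here. Peaks had been listed for each line separately, and 4 of the lists carry the mark qcTrimmed, which the L1236 list lacks. The score of each peak in the deposited files is the authors' peak area, a whole number that rises with peak width, with no stated scaling to depth. All scores were divisible by 8. Because no scale common to the lists is given, comparisons used scores only as ranks or percentiles within a list. Scores per bp and the mitochondrial share of the summed score only describe each list. The lowest score per bp in a list ranged from 3.67 in Reh to 12.0 in L1236, and whether the lists were held to the same threshold is not known.

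Positions are 1-based and inclusive, in hg18, as the files give them. The lists held 25865 (L1236), 23329 (L428), 26662 (L591), 28043 (Reh) and 5793 (Namalwa) peaks, of which those on chromosomes 1 to 22 and X entered the comparisons. Mitochondrial peaks were set apart and are described after the report. Peaks overlapped when they shared at least 1 bp. Pairs of lists were compared by the percentage of peaks overlapping and by the Jaccard index over bases, against 100 circular shifts within each chromosome (random seed 7). Overlapping peaks of all lines were joined into merged regions, and a line counted as present in a region if any of its peaks was part of it. Hodgkin-only regions had a peak in all 3 Hodgkin lines and in neither non-Hodgkin line, and non-Hodgkin-only regions had the opposite. Their counts were set against the count under independence, the product of each line's frequency of presence or absence over the merged regions. Because each merged region holds at least 1 peak, a ratio of 1 is not the value without any association, and ratios were read against those of the other splits. Groups were compared by exact permutation over the 10 splits of the lines into 3 and 2, one-sided except for chromosome shares, with 0.1 as the smallest possible p. These p-values measure the spread between cell lines. Shares of counts have exact Clopper-Pearson intervals at 95%.

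Regions named in the text followed a rule fixed before the data were examined. They are the 10 Hodgkin-only, the 10 non-Hodgkin-only and the 10 regions of all 5 lines with the highest value of the lowest score percentile over the lines with a peak. The 5 windows of 1 Mb with the most regions of each class were also named. Peaks of chromosome Y were left out throughout. Tests of promoter overlap, of 15 gene lists and of 18 sequence motifs had been fixed in advance and were not run, since no hg18 sequence or gene annotation was used here. Gene names are not given for the same reason.

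Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The merging and class counts were tested on simulated lists with a planted Hodgkin and non-Hodgkin class. Over 61859 simulated regions the count of either class was 100.0% of the count planted, and the planted split ranked 1. Simulated sites were spaced so that peaks of different sites never touched, so the joining of neighbouring sites was not tested. Alternatives covered the overlap rule (50% of the shorter peak, or centres within 250 bp), peak width (200 bp around the centre) and list length (the highest-scoring 5760 peaks, or the upper 50%). They also covered joining of peaks up to 200 bp apart, chromosome X, class definition, window size, peak width in place of score, and each line left out in turn. Permutations of regions and bootstraps over chromosomes in the closing part numbered 1000 each.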

Results

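DNase I cuts DNA where chromatin is open, so sequencing the released fragments maps the accessible sites of a genome. Peaks of accessibility were compared in 5 human cell lines of B-lineage malignancies. L1236, L428 and L591 came from Hodgkin lymphoma, whose malignant cells derive from B cells that have lost much of the B cell programme. Reh came from a pro-B lymphoblastic leukaemia and Namalwa from a Burkitt lymphoma, and the labels place both in the non-Hodgkin group. Each line gave 1 library and 1 deposited peak list, so the 3 Hodgkin and 2 non-Hodgkin lines served as the replicates of their group and no error within a line was available. The lists held no read counts, so the depth behind each list is unknown.

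On chromosomes 1 to 22 and X, the L1236 list held 25646 peaks, the L428 list 23288, the L591 list 26612 and the Reh list 27925. The Namalwa list was much shorter, with 5760 peaks covering 2.03 Mb. The covered length was 9.90 Mb in L1236, 11.2 Mb in Reh and 14.3 Mb in L591, where the median peak was 450 bp wide. Median widths in the other lines lay between 290 bp in Namalwa and 320 bp in L428 and Reh. The short Namalwa list limits every count that requires a Namalwa peak or its absence. DNase I had been used at 6 U/ml for L1236, L428 and Reh and at 12 U/ml for L591 and Namalwa, after titration for each line.

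The first comparison asked how far the accessible sites of the lines coincided. L428 and L591 were the most alike, with a Jaccard index over bases of 0.362, and 67.4% of L428 peaks overlapped an L591 peak. L591 and Reh followed at 0.279, and L428 and Reh reached 0.246, above the 0.229 of L1236 with L428 and the 0.228 of L1236 with L591. By this index L1236 was less like L428 and L591 than either of them was like Reh, and the order held with lists of equal length (0.211 and 0.212 against 0.281 and 0.331). The 5000 highest-scoring regions gave a mixed order. Those of L428 were found at 73.3% in L1236 and 66.7% in Reh, and those of L591 at 79.1% and 76.6%. In the other direction, those of L1236 were found at 61.5% in L428 and 63.3% in L591, and those of Reh at 80.3% and 84.7%. Nearly all Namalwa peaks, 98.4%, overlapped a Reh peak, whereas 83.0% overlapped an L591 peak, 76.2% an L428 peak and 65.8% an L1236 peak. Each of the 10 pairs overlapped 80.3 to 243 times as much as the mean of 100 circular shifts of the list within each chromosome, where the Jaccard index never exceeded 0.00366. The index of pairs with Namalwa, 0.118 to 0.176, is held down by the length of its list. With lists of equal length, Reh with Namalwa had the highest index of the 10 pairs, 0.359 against 0.351 for L428 with L591.

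**Figure D1:**
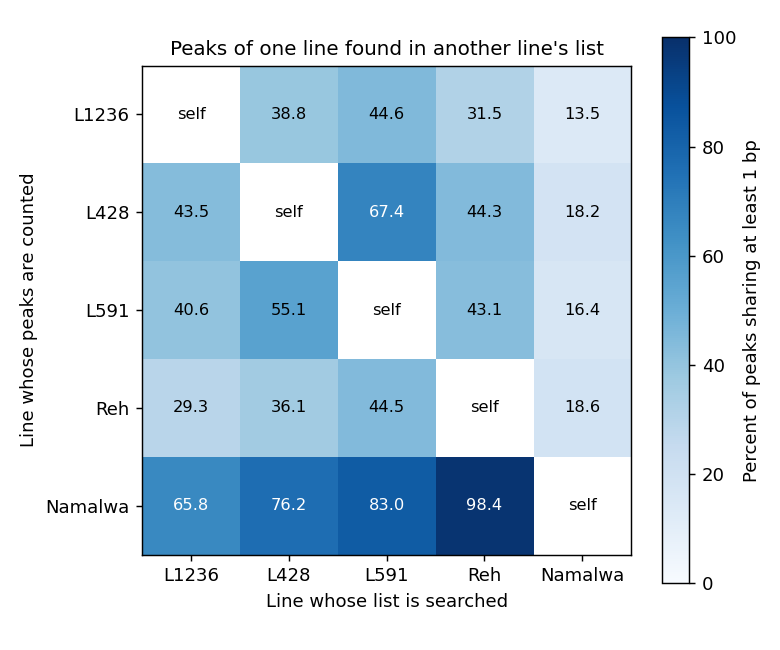
Percentage of the peaks of each line (vertical axis) that share at least 1 bp with a peak of another line (horizontal axis), with colour giving the same percentage. Namalwa peaks reach 98.4% in Reh, and L428 reaches 67.4% in L591.

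Peak scores followed the same order in some pairs of lines and less so in others. Across the regions with a peak in both lines, Spearman's rho of the deposited score was 0.733 for Reh with Namalwa, 0.628 for L591 with Reh and 0.592 for L428 with L591. Those of L1236 ran from 0.356 with Reh to 0.406 with Namalwa, but each pair rests on its own set of regions. Over the 3030 regions with a peak in all 5 lines, rho was 0.759 for Reh with Namalwa and 0.711 for L428 with L591, and L1236 reached 0.536 with L591 and 0.481 with L428. Pairs of a Hodgkin and a non-Hodgkin line ranged on this set from 0.403 for L1236 with Reh to 0.595 for L591 with Reh. These values are across regions within a pair of libraries, and regions are not independent replicates, so no p-value was attached to them.

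The Hodgkin lines were on average more alike than lines of different groups, but another grouping of the same lines gave a larger difference. The mean Jaccard index was 0.273 over the 3 Hodgkin pairs and 0.176 for the non-Hodgkin pair, and pairs between groups ranged from 0.118 to 0.279. Within-group pairs exceeded between-group pairs by 0.0668. In a one-sided exact permutation test over the 10 splits of the lines into 3 and 2, 2 splits were as large (p = 0.2, where 0.1 is the smallest p the design allows). The larger split joined L428, L591 and Reh, with a difference of 0.0711. The rank of the real split changed with the measure: it was first of the 10 (exact permutation p = 0.1) with lists of equal length and with peaks set to 200 bp, and 5 of 10 were as large (p = 0.5) by the share of the smaller list. With lists of equal length the first rank rests in part on Reh with Namalwa, whose index rose to 0.359. A common source of these libraries was not excluded. The split by DNase I concentration gave -0.0316, and among the lines digested at 6 U/ml the index of L1236 with L428 (0.229) lay between those of L1236 with Reh (0.166) and L428 with Reh (0.246). At 12 U/ml there was 1 line of each group, so no within-group pair could be formed. Leaving out a line moved the difference to 0.0319 without L428, 0.0288 without L591, 0.139 without Reh and 0.0426 without Namalwa.

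Accessibility shared by all 3 Hodgkin lines and absent from both non-Hodgkin lists was found at 2566 of the 59212 merged regions (4.33%, exact 95% interval 4.17 to 4.50, counting error only). The region with the highest score percentile in all 3 lists lay on chromosome 2 at 98857841 to 98858880 (hg18), at percentile 97.6 in L1236, 99.1 in L428 and 98.8 in L591. Chromosome 2 held 3 more of the 10 leading regions, at 38117881 to 38119680, 64686961 to 64688050 and 102210401 to 102211000. Chromosome 7 held regions at 55343961 to 55344880 and 5547141 to 5548510, and chromosome 3 at 33008671 to 33010090 and 162086081 to 162087440. The remaining leading regions were on chromosome 5 at 169193401 to 169194480 and on chromosome X at 118665801 to 118666720. All 10 ranked in the upper part of each Hodgkin list, with a lowest percentile of 96.1. Across the whole class the median percentile was 64.6 in L1236, 60.8 in L428 and 60.5 in L591. No hg18 gene annotation was used here, so regions are given by position without genes.

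The count of 2566 was the highest of the 10 possible groups of 3 lines, ahead of 2100 regions with peaks in L428, L591 and Reh alone (one-sided exact permutation p = 0.1, the smallest the design allows). Groups with Namalwa had 233 regions or fewer and could hardly lead, since its list is short and lies almost wholly in the Reh list. The comparison is therefore mainly among the groups without Namalwa, and the requirement of no Namalwa peak decides its order. That requirement removed 693 regions of L428, L591 and Reh without L1236, but 6 regions of the Hodgkin lines without Reh. With Namalwa ignored, L428, L591 and Reh had more regions to themselves than the 2572 of the Hodgkin lines. The count of 2566 was 1.29 times the 1983 regions that independent calls in each line would give. The ratio of every other group of 3 lines was lower, at 0.941 or less. Without L1236 the Hodgkin-only count was 5998, without L428 4143 and without Reh 4968. The ratio to independence was 0.757 without L428, 0.801 without L591 and 0.888 without Reh. Leaving out a line changes the merged regions, and ratios of other splits were not calculated there. These ratios therefore do not show a loss of association. With the lists limited to their 5760 highest-scoring peaks, 367 regions were Hodgkin-only and 1020 were non-Hodgkin-only, so that the order of the counts of the classes turned round, and with the upper 50% of each list the counts were 1097 and 252. The Hodgkin lines no longer led the 10 splits in either setting (exact permutation p = 0.2 for count and ratio). With lists of equal length, L591, Reh and Namalwa had 389 regions to themselves (ratio 1.32 against 1.04), and with the upper 50%, L428, L591 and Reh had 1512 (1.26 against 1.02).

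**Figure D2:**
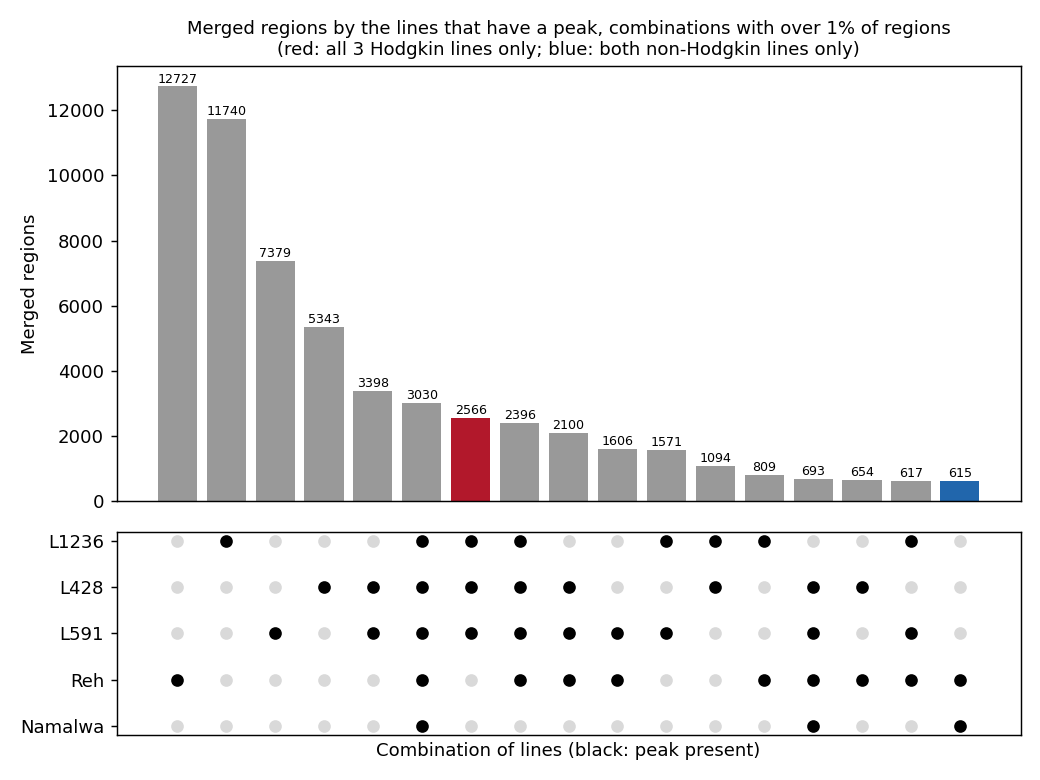
Number of merged regions (bars, vertical axis) for each combination of lines with a peak (black dots under each bar), for combinations with over 1% of the regions. Regions of all 3 Hodgkin lines alone numbered 2566 (red) and regions of Reh and Namalwa alone 615 (blue), and the tallest bars are regions seen in 1 line.

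Regions accessible in both non-Hodgkin lines and in no Hodgkin line numbered 615. The leading region was on chromosome 4 at 40691 to 42520, at percentile 99.7 in Reh and 98.4 in Namalwa, and a neighbouring region at 42701 to 45030 was also among the 10 leading ones. Chromosome 15 held the regions next in rank, at 96304351 to 96305040 and 19248111 to 19250450. Others lay on chromosome 17 at 21945591 to 21945750, chromosome 5 at 139029601 to 139030770, chromosome 7 at 98108681 to 98109840, chromosome 8 at 145465031 to 145466730, chromosome 1 at 44074621 to 44075190 and chromosome 3 at 171012761 to 171013880. The class had a median percentile of 80.5 in Reh and 30.0 in Namalwa. The count was 1.32 times that under independence, the highest ratio of the 10 splits, but 7 of the 10 pairs of lines had as many regions to themselves (exact permutation p = 0.7 for the count and 0.1 for the ratio). Without Namalwa, 13355 regions had a Reh peak and no Hodgkin peak, at 2.43 times independence. Every merged region without a Hodgkin peak must then have a Reh peak, which raises this ratio, so it is not comparable with 1.32. Without L428 the ratio of the class was 0.991, with no ratios of other splits to read it against. With lists of equal length the ratio was 2.42, and the count of 1020 was the highest of the 10 splits (next 568, exact permutation p = 0.1). With the upper 50% of each list, 7 of the 10 were again as large (count 252, exact permutation p = 0.7). Because 98.4% of Namalwa peaks also lay in the Reh list and a common source of these libraries was not excluded, the class, its ratio and the score correlation of 0.733 are not shown to be agreement between 2 independent lines.

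Regions with a peak in all 5 lines numbered 3030, or 5.12% of merged regions. Their median score percentile was 92.7 in Reh, 90.4 in L591, 85.9 in L428 and 78.3 in L1236, and 64.4 in Namalwa, where they made up 3030 of 5000 regions. The leading region spanned 554211 to 560270 on chromosome 1, with 14410 score units per bp in L1236 and 1450 in Namalwa, against a median over all peaks of 19.4 and 7.12. The following regions lay on chromosome 1 at 121182221 to 121187060, chromosome 7 at 61604481 to 61611950 and chromosome 5 at 134286821 to 134292160. Further leading regions were on chromosome 16 at 44943201 to 44973520, chromosome 6 at 58881471 to 58888220, chromosome 11 at 10485891 to 10488450, chromosome 5 at 79981961 to 79984010, chromosome 10 at 41702281 to 41717400 and chromosome 13 at 108874351 to 108874800. Whether reads at these regions map to repeated sequence, or to sequence resembling mitochondrial DNA, was not tested, so a peak there is not shown to be open chromatin.

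Most merged regions, 62.9%, had a peak in 1 line alone. Reh had 12727 such regions (48.8% of its regions, exact 95% interval 48.2 to 49.5) and L1236 had 11740 (48.2%, 47.6 to 48.9). The shares were lower in L591, at 28.6% (28.1 to 29.2), and in L428, at 24.7% (24.2 to 25.3). Namalwa had 36 of 5000 (0.72%, 0.505 to 0.995), a share that was 4.50% with centres within 250 bp and 6.63% with peaks set to 200 bp. Line-specific regions tended to rank low in their lists, with median percentiles from 7.67 in Namalwa to 39.4 in L1236. Not all were weak, since 1403 of the 5000 leading L1236 regions had no peak in any other line. The intervals cover counting error only, and with lists of equal length the share was 17.0% in Reh and 17.4% in Namalwa, while L1236 was highest at 50.6%.

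Hodgkin-only regions were spread widely, over 1163 of the 2748 windows of 1 Mb that held any merged region, and 102 windows held 5 or more. The 1 Mb window with the most was chromosome 6 from 138 to 139 Mb, with 17 Hodgkin-only regions, where L428 had 167 regions, L591 86, L1236 20, Reh 5 and Namalwa 1. Chromosome 8 from 129 to 130 Mb followed with 16, where L1236 had 52 regions, L591 51 and L428 36, and neither Reh nor Namalwa had any. Windows on chromosome 2 from 64 to 65 Mb, chromosome 3 from 123 to 124 Mb and chromosome 17 from 35 to 36 Mb held 13 each. Non-Hodgkin-only regions were most frequent on chromosome 7 from 1 to 2 Mb and chromosome 19 from 41 to 42 Mb, with 9 each, followed by chromosome 4 from 0 to 1 Mb and chromosome 8 from 86 to 87 Mb with 8 and chromosome 1 from 1 to 2 Mb with 7. Copy number and accessibility can both affect the number of peaks in a window and were not separated. In 5 Mb windows the leading stretch moved to chromosome 8 from 125 to 130 Mb, with 28 Hodgkin-only regions.

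**Figure D3:**
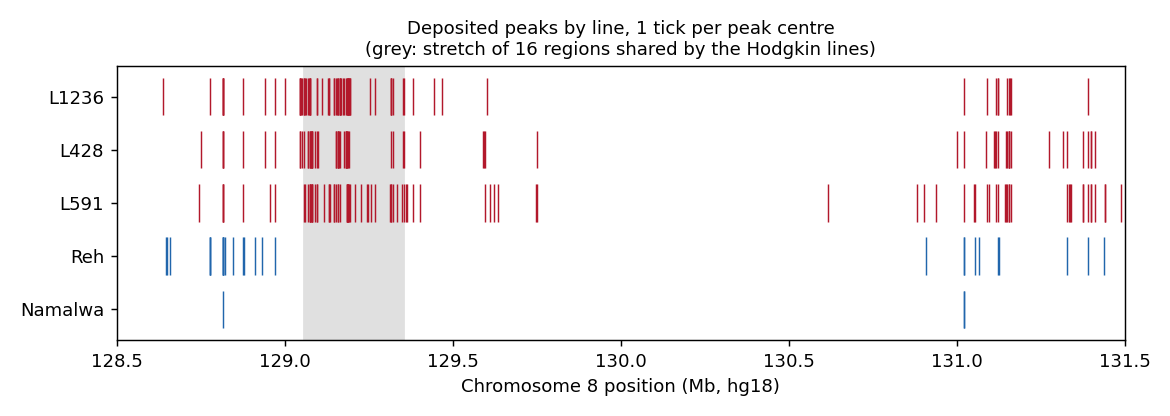
Deposited peaks of the 5 lines along part of chromosome 8 (horizontal axis, position in Mb, hg18), with 1 tick per peak centre, Hodgkin lines in red and non-Hodgkin lines in blue. In the grey stretch, from 129056821 to 129356040, L1236 has 42 merged regions, L428 28 and L591 41, and Reh and Namalwa have 0.

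The lists also differed in how their peaks were spread over chromosomes, a comparison made after the data had been seen. Chromosome 2 held 9.82% ± 0.470 (SD, n = 3) of the peaks of the Hodgkin lines and a mean of 6.37% in Reh and Namalwa (6.49% and 6.25%). The Hodgkin share was also higher on chromosome 5, at 5.65% ± 0.150 against 3.81%, and on chromosome 3, at 6.19% ± 0.400 against 4.58%. Chromosome 19 went the other way, with 4.61% ± 0.172 in the Hodgkin lines, 6.87% in Reh and 9.27% in Namalwa, and the difference of -3.46 percentage points shrank to -2.26 without Namalwa. Chromosomes 7 and 16 were likewise lower in the Hodgkin lines, at 5.83% ± 0.826 against 7.65% and 3.66% ± 0.314 against 4.91%. The order on chromosomes 2 and 19 was the same at each DNase I concentration, but it had to be. Every Hodgkin line lay beyond both non-Hodgkin lines there, so any subset keeps the order and an effect of concentration was not tested. At 6 U/ml, chromosome 2 held 9.85% in L1236 and 9.33% in L428 against 6.49% in Reh, and chromosome 19 held 4.73% and 4.41% against 6.87%. At 12 U/ml, chromosome 2 held 10.3% in L591 against 6.25% in Namalwa, and chromosome 19 held 4.67% against 9.27%. All 3 Hodgkin lines lay above both non-Hodgkin lines on 7 of 23 chromosomes and below them on 6, where chance separates 4.6 if the lines are independent. Almost all Namalwa peaks lay in the Reh list, and if these lines are not independent the chance value is higher. The smallest two-sided exact permutation p was 0.1, the lowest the design allows, and its Benjamini-Hochberg value over the 23 chromosomes was 0.23, so no single chromosome passed.

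**Figure D4:**
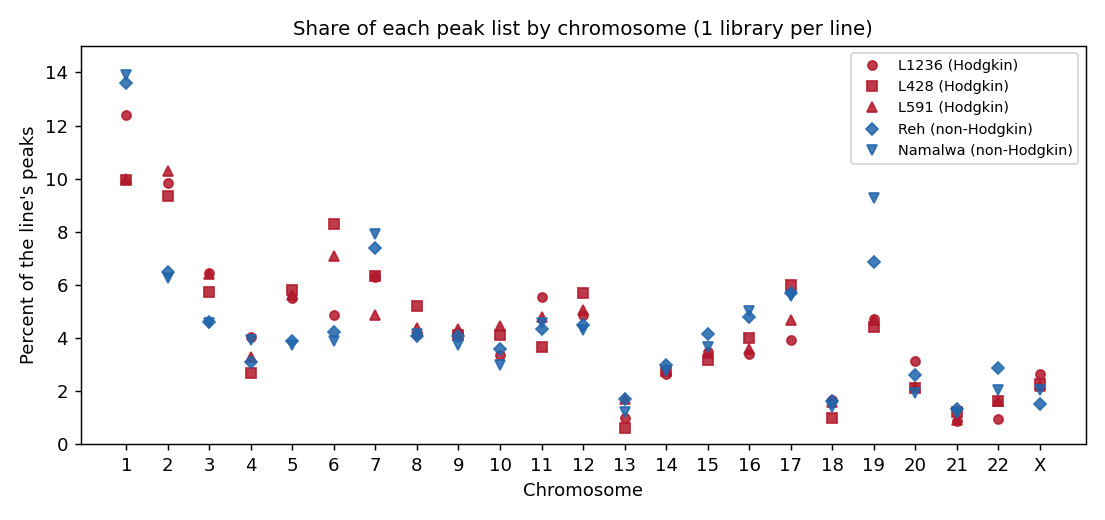
Percentage of the peaks of each line (vertical axis) on each chromosome (horizontal axis), with 1 point per line, Hodgkin lines in red and non-Hodgkin lines in blue. On chromosome 2 the Hodgkin lines lie between 9.33% and 10.3%, above Reh and Namalwa, and on chromosome 19 they lie between 4.41% and 4.73%, below both.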

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

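The tests of the Namalwa and Reh lists, of the chromosome 8 stretch and of chance placement of neighbouring regions were chosen after the results had been seen, and the 20 kb distance was taken after 10, 20 and 50 kb had been looked at. The tests that restrict Hodgkin-only regions to those near a Reh region or join close peaks were chosen before their results were seen.

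Mitochondrial DNA, which entered no comparison, took 52.8% of the summed peak score in L1236, 68.7% in L428, 64.6% in L591, 46.2% in Reh and 68.3% in Namalwa. These sums come from 2 mitochondrial peaks per line covering 16440 to 16510 bp, with a mean score per bp of 32340 in L1236, 22630 in L428, 29190 in L591, 6577 in Reh and 4847 in Namalwa. On the other chromosomes the mean score per bp was 47.2, 19.5, 18.4, 11.2 and 18.2 in the same order of lines.

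The Namalwa list lay almost wholly inside the Reh list: 98.7% of 5000 Namalwa regions overlapped a Reh region, and 3 of the 67 outside scored above the Namalwa median. For the 5000 leading regions of each line, the next highest of the 20 ordered pairs was L428 in L591 at 92.4%, and the highest between groups was Reh in L591 at 84.7%. Low depth of the Namalwa library as the whole cause was argued against over the 3030 regions of all 5 lines. Namalwa scores there had a Spearman rho with Reh that was 0.255 above their highest with a Hodgkin line (95% interval 0.204 to 0.306 from 1000 bootstraps over 23 chromosomes). The argument also required that Hodgkin lines not be closest to Reh, and 0 of them had a higher rho with Reh than with their nearest Hodgkin line. Over the regions shared by each pair this condition failed for L591, with 0.628 for Reh against 0.592 for L428. The argument is therefore limited to the regions of all 5 lines. Read depth is unknown, and low depth as a part of the cause was not tested. Reh material in the Namalwa library or a mix-up of these libraries, and accessible chromatin shared by non-Hodgkin lines, both predict a rho with Reh (0.759) above those of other pairs (highest 0.711, between groups 0.595), and cannot be told apart with 1 non-Hodgkin pair. Under narrower rules, added after seeing the data, the percentage of Namalwa peaks in Reh was 87.4 with centres within 250 bp and 81.5 with peaks set to 200 bp.

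Hodgkin-only regions lay close to each other: 750 of 2566 had another within 20 kb, against a mean of 404 and a highest of 495 in 1000 permutations of the class among the regions of each chromosome. The count also exceeded all permutations at 10 kb (570 against a highest of 353) and at 50 kb (1073 against 774), while regions of L428, L591 and Reh alone did not (327 at 20 kb, mean 288, highest 365, permutation p = 0.04). Closeness was not particular to the Hodgkin-only class. Of 615 non-Hodgkin-only regions, 164 had another within 20 kb (permuted mean 33.8, highest 58), 4.85 times the mean against 1.86 times for Hodgkin-only regions. Loss of DNA in Reh as the whole cause was argued against by the 1512 Hodgkin-only regions with a Reh region within 50 kb, of which 452 had a neighbour (highest permuted 270). Stretches split by gaps of up to 2 kb were argued against as the whole cause in the same way. After peaks up to 2 kb apart had been joined, 452 of 2201 regions had a neighbour (highest permuted 228), a count that equals the previous one by coincidence. The share with a neighbour fell from 29.2% to 20.5% on joining. Stretches split by wider gaps were not tested. Gain of DNA in the Hodgkin lines and accessibility shared over wider domains were not tested, and no biological explanation is drawn.

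On chromosome 8, 16 consecutive regions with peaks in all 3 Hodgkin lines, from 129056821 to 129356040, had no Reh peak. A chance run was argued against (permutation p = 0.001, the smallest that 1000 permutations can give, highest permuted run 15). The permutations place missing peaks independently of each other within a chromosome. Hodgkin-only regions lay close to each other in general, so the p-value does not show that this stretch exceeds such clustering. The same scan of the 4 longer lists gave a run of 8 regions without an L428 peak on chromosome X from 133768611 to 148393280 (permutation p = 0.001), and runs of 12 without Reh on chromosome 2 (p = 0.038) and of 4 without L591 on chromosomes 8 and 16 (p = 0.036), but these are runs of shared regions, and their spans held 19 other L428 regions, 10 of Reh and 0 to 18 of L591. No Reh region lay in 1935 kb around the stretch, from 128972080 to 130907461, where L1236 had 52 regions, L428 36 and L591 54. Loss of DNA in Reh could give such a gap, and so could closed chromatin there; these cannot be told apart from peak lists, which hold no read counts between peaks.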

How the results depend on the processing

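Alternatives for chromosome shares, for Namalwa peaks in Reh, for peak numbers without chromosome X, for named regions and for the rank of class counts among splits were added after seeing the data; the others were set before. Mean overlap, group similarity, class counts and the line-specific share over all lines kept their size under the 50% overlap rule, centres within 250 bp and chromosomes 1 to 22, and class counts also under joining at 200 bp, which was run for the classes and named regions alone. The Namalwa line-specific share rose from 0.72% to 4.50% with centres within 250 bp and 6.63% with peaks set to 200 bp. Mean Jaccard overlap moved from 0.209 to 0.121 with peaks set to 200 bp and to 0.598 as share of the smaller list, another measure. Hodgkin-only and non-Hodgkin-only counts of 2566 and 615 became 367 and 1020 with lists of equal length and 1097 and 252 with the upper 50%, where fewer peaks enter. A class of at least 2 of 3 Hodgkin lines held 8629 regions by construction. The densest window held 28 Hodgkin-only regions at 5 Mb, against 17 at 1 Mb. With each line left out, Hodgkin-only counts ranged from 2572 to 5998, non-Hodgkin-only counts from 685 to 13355 and the within-minus-between difference from 0.0288 to 0.139. Ratios to independence ranged from 0.757 to 1.26 for Hodgkin-only regions (0.801 without L591, 0.888 without Reh) and from 0.991 to 2.43 for non-Hodgkin-only regions. The cause of these changes was not tested. Ratios of other splits were not calculated with a line left out, so a ratio below 1 there does not show a loss of association. The 2.43 came without Namalwa, where every region lacking a Hodgkin peak must have a Reh peak, so it is not comparable with the ratio over both lines. Of the values answering a comparison, 45 were labelled as staying and 12 as moving. Of the others, 161 were labelled as staying, 28 as moving, and 4, all ratios, went from above to below 1. The rule for these labels differed between results, so the tally does not measure stability of size. The within-minus-between difference of 0.0668 was labelled as staying at 0.0288 (without L591) and 0.139 (without Reh). The Namalwa line-specific share was so labelled at 6.63%. Namalwa peaks in Reh were labelled as moving from 98.4% to 99.5% with the upper 50% of the Reh and Namalwa lists. All 10 named Hodgkin-only regions kept their class in each alternative except without chromosome X, which held 1 of them. With shorter lists, a line left out or 2 of 3 lines this was all but fixed in advance. The regions rank high in every Hodgkin list and hold no other peak. The overlap, peak width and joining rules were the settings that could have changed it. The differences on chromosomes 2, 3, 5, 7, 16 and 19 kept direction and separation with lists of equal length and with the upper 50%. They also did so with each line left out, but groups already separated must stay so, and those settings were no test. No paired analysis was possible because the labels pair no lines and give no replicate numbers. Promoter, gene list and motif alternatives were not run. Unknown depth limits each absence of a peak, and the Namalwa list was the shortest.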

Other observations

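The values here were chosen after the data had been seen. Chained at 20 kb, the largest cluster of Hodgkin-only regions held 9 and spanned 210905061 to 210962950 on chromosome 1, where L1236 had 30 regions, L591 15, L428 11, Reh 1 and Namalwa 0. A cluster of 8 lay on chromosome 3 from 123276181 to 123306490. Clusters of 7 lay on chromosome 2 from 191251381 to 191296310 and from 231231601 to 231242290, and on chromosome 5 from 131428321 to 131467990, all without a Reh or Namalwa region. The largest cluster of non-Hodgkin-only regions held 9, on chromosome 19 from 41451881 to 41488970, where Reh had 49 regions, L428 1 and L1236 and L591 0. Non-Hodgkin-only regions lay close together as well, with 164 of 615 within 20 kb of another against a highest permuted count of 58.

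Some windows of 1 Mb held many regions in 1 line and few in the others. L1236, whose list lacks the qcTrimmed mark, had 158 regions on chromosome 7 from 61 to 62 Mb, where Reh had 20, Namalwa 5 and L428 and L591 3 each. It had 116 on chromosome X from 61 to 62 Mb and 100 on chromosome 11 from 48 to 49 Mb, where no other line exceeded 4. Lists with the mark had such windows too, with 120 Reh regions on chromosome 1 from 141 to 142 Mb, where no other line exceeded 12, and 37 L428 regions on chromosome 7 from 124 to 125 Mb, where no other line exceeded 4. Whether the processing of the L1236 list differed was not tested. Conversely, L1236 had 0 regions on chromosome 9 from 138 to 139 Mb, where Reh had 54, L591 23 and L428 22. L428 had 0 on chromosome 18 from 58 to 59 Mb, where L1236 had 32. Runs of missing L1236 peaks were matched by permutation, the longest being 12 regions on chromosome 22 from 41582961 to 45024990 (permutation p = 0.078).

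The share of Reh regions with a Namalwa peak rose with the Reh score, from 0.302% in the lowest of 10 score classes to 53.2% in the ninth and 89.8% in the highest. Of the 5000 leading regions of each line, 1403 in L1236, the list without the qcTrimmed mark, had no peak in any other line, against 286 in Reh, 237 in L428, 201 in L591 and 36 in Namalwa.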
